A study of Mus musculus with 7 samples.

How the data were processed

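Messenger RNA selected by poly(A) was sequenced on an Illumina HiSeq2000 from 7 libraries of mouse cells in 3 groups: undifferentiated Ago2-knockout ES cells, wild-type XEN cells and Ago2-knockout XEN cells. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.4.2a and counted per gene with featureCounts 1.4.5-p1. The deposited values are raw read counts per Ensembl gene, without normalization, for 43629 genes and 7 libraries, and they are whole numbers in every column. Libraries are reverse-stranded per the labels, whereas the strand setting of the counting, the annotation release and any filter are not stated, so that counts of overlapping antisense genes and of close paralogs are uncertain. Wild-type ES cells belong to another series and are not used here.

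Groups and lines were read from the sample titles. Lines C4 and 5-3 each have a library in KO ESC and in KO XEN, and 5-3 has 2 in KO ESC. The pairing rests on the labelled line: the difference of C4 from 5-3 in ES cells and that in XEN cells correlated across 18426 genes with r of 0.0797. Line is not in the model and was added as a block in an alternative. The block places wild-type cells midway between C4 and 5-3. Line lies within genotype, so in comparisons with WT XEN the block cannot separate line from genotype. Symbols, positions and biotypes come from GENCODE release M21 (GRCm38, the same assembly as mm10), which matched 42462 of the IDs. The 1167 IDs with no symbol held 0.154% of counts and were kept in the tests.

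Tests ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. All 7 libraries entered a single edgeR quasi-likelihood fit with 3 groups, TMM scaling and filterByExpr by group, which left 18426 genes and set aside 25203. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The fit had 4 residual and a median of 3.92 prior degrees of freedom, and a common biological coefficient of variation of 0.268. P-values measure the spread between libraries, and the labels do not say whether libraries of a group came from separate cultures. CPM values use the TMM-scaled library sizes. Where a group had 0 counts, folds are lower bounds against a floor of 3 counts over the group, which is 0.0225 CPM in KO ESC, 0.0413 in WT XEN and 0.0648 in KO XEN, and with 1 to 3 counts a ratio with its exact 95% interval is given. These intervals and floors cover counting error only. The interaction of line and differentiation used 5 groups, with 2 residual degrees of freedom.

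The comparisons, the 27 gene lists with 618 entries, the naming rule and the alternative settings, apart from those named below as added, were fixed before the data were examined. List symbols with no match numbered 2, Zscan4a and Peg13, and 1 was matched through a synonym. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry, which asks if the genes of a list move on balance in a direction and compares them with no other genes. Some genes stand in more than 1 list. Named genes are the 4 Argonaute genes; per comparison the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups, without predicted genes; up to 4 members per list with the smallest adjusted p, with any member that goes against its list; and up to 5 genes for the difference between lines, of which none passed. Other genes are marked as chosen after their values were seen. Not every list member that the rule allows is named, and 1 is not reported here.

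The pipeline was tested on simulated counts with the depths and spread of these libraries and 100 changed genes per fold among 18426. In the data 46.2% to 69.0% of genes were called, which makes the Benjamini-Hochberg cutoff less strict than in the simulation. The simulated rates are thus not the sensitivity of the comparisons themselves. For KO XEN against WT XEN it called 7% of genes with a 2-fold and 53% with a 4-fold change, for KO XEN against KO ESC 17% and 68%, and for WT XEN against KO ESC 16% and 67%, with 5, 10 and 7 false calls and 0 in the wrong direction. A raised list gave camera p of 5.13e-38, 4.18e-51 and 1.94e-47, and an unchanged list 0.43, 0.203 and 0.198. A single simulated list of each kind does not show whether camera p-values hold where list members are correlated. In KO XEN against WT XEN the estimated correlation ran from -0.0346 (blood and endothelium) to 0.824 (2-cell-like state). Of the 18 lists that camera called there at the preset correlation, 0 passed with the estimated correlation. That setting also takes its reference from the 4 residual degrees of freedom, so that p rises even without correlation. For ES cell microRNA targets in KO XEN against KO ESC the estimate was -0.022, below the preset, yet camera p rose from 8.63e-07 to 0.00581. The lost calls thus do not show by themselves that correlation among members accounts for a list result.

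Alternative settings were DESeq2 size factors, library size alone, no filter on low counts, the DESeq2 Wald test, a fit of only the 2 groups compared, line as a block, the 2 undifferentiated 5-3 libraries summed, an absolute log2 fold change of at least 1, for the correlation of changes only genes with a mean of at least 10 CPM in the highest group, and leaving out each library in turn. A fit without both C4 libraries and a thinning of every library to the smallest total were added after seeing the data, as was the search for microRNA sites, set up before its own result was seen. For microRNA sites, 3' untranslated regions were taken from the annotation for 10215 genes and searched for 7-base seed matches of 6 families, with control 7-mers of the same base composition and CpG count. No comparison has 3 libraries on both sides, so that other splits of the samples were not counted.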

Results

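Messenger RNA was sequenced from 7 libraries of mouse embryonic stem (ES) cells of the E14 line and its derivatives, in 3 groups. Undifferentiated Ago2-knockout ES cells (KO ESC) gave 3 libraries, C4, 5-3_1 and 5-3_2, named after the knockout lines C4 and 5-3. Wild-type E14 cells differentiated towards extra-embryonic endoderm (WT XEN) gave 2 libraries, A and B, and knockout cells differentiated in the same way (KO XEN) gave 2, C4 and 5-3. Differentiation lasted 5 days in serum with 0.1 µM all-trans retinoic acid and 10 ng/mL activin A. Total counts were 40327397, 39998808 and 48650113 in KO ESC, 36427340 and 38595537 in WT XEN, and 13941826 (C4) and 33389566 (5-3) in KO XEN. Levels are given as CPM, counts scaled to a common library size, as mean ± SD over n = 3 KO ESC, n = 2 WT XEN and n = 2 KO XEN libraries, and log2 fold changes as estimate ± SE, also where they follow a gene in parentheses. Mitochondrial transcripts held 0.781% and 0.979% of counts in KO XEN, 1.94% and 2.64% in WT XEN, and 2.79% to 3.26% in KO ESC.

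Ago2 encodes the Argonaute protein that binds microRNAs and can cleave matched transcripts (ENSMUSG00000036698, chromosome 15, 73095844 to 73184935, mm10). Its transcript stood at 394 and 432 CPM in WT XEN libraries A and B. In KO XEN it was 9.94 CPM in line 5-3 and 122 CPM in the library labelled C4, and in KO ESC it was 9.37 and 9.65 CPM in line 5-3 and 94.4 CPM in C4. The 2 lines differed in this transcript, and KO XEN and WT XEN did not differ past the threshold for Ago2 (log2 fold change -2.66 ± 1.36, adjusted p = 0.145, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). With line as a block, which takes the difference of C4 from 5-3 out of the spread, the log2 fold change was -3.56 (adjusted p = 9.62e-05). Without both C4 libraries, which leaves only 5-3 in KO XEN, the log2 fold change was -5.38. Adjusted p over the edgeR and DESeq2 alternatives ranged from 9.62e-05 to 0.369. Ago3, another Argonaute gene (ENSMUSG00000028842, chromosome 4, 126331704 to 126429556), was lower in KO XEN at 12.8 ± 2.49 CPM than in WT XEN at 34.7 ± 10.4 CPM (log2 fold change -1.44 ± 0.31, adjusted p = 0.00637, same test). Ago1 stood at 89.8 ± 9.12 CPM in KO XEN and 66.3 ± 4.05 in WT XEN (log2 fold change 0.44 ± 0.24, adjusted p = 0.173), and Ago4 at 3.69 ± 0.219 and 7.25 ± 3.78 CPM (-0.97 ± 0.47, adjusted p = 0.127), neither past the edgeR threshold. Both results depended on the libraries kept. Ago1 passed without KO ESC C4 (adjusted p = 0.0333, range 0.0333 to 0.568), with its log2 fold change still at 0.44. That library is in neither group compared here and enters only through the shared fit. Without both C4 libraries the log2 fold change of Ago1 was 0.54. Ago4 passed without WT XEN A, which leaves only B in WT XEN, with a log2 fold change of -1.49.

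**Figure D1:**
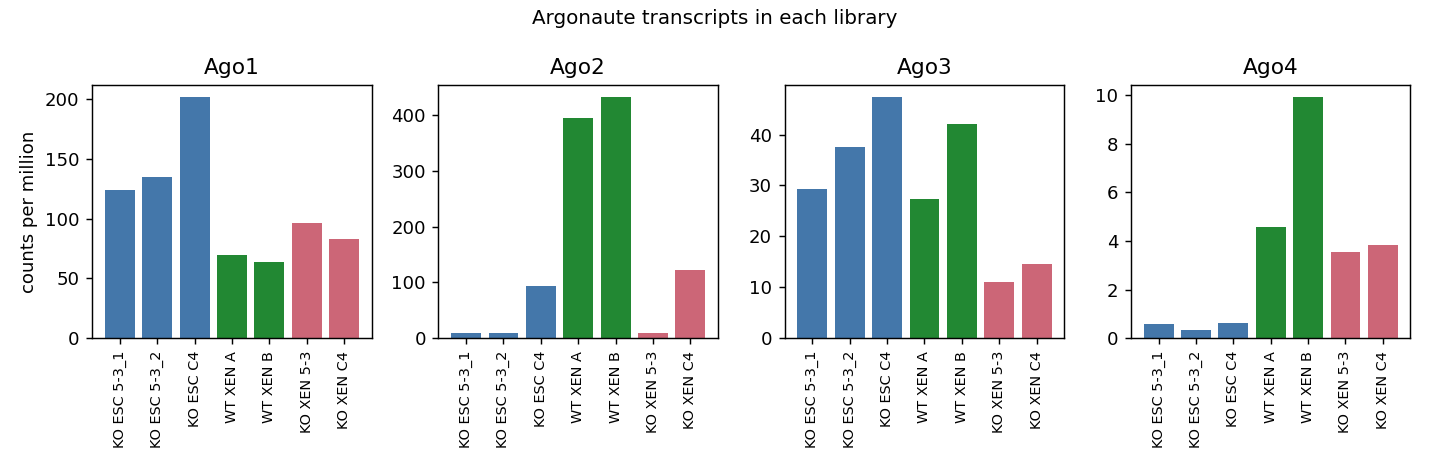
Level of Ago1, Ago2, Ago3 and Ago4 in each of the 7 libraries, as CPM on a linear axis that starts at 0, 1 bar per library. Ago2 reached 394 and 432 CPM in WT XEN, 122 in C4 KO XEN and 9.94 in 5-3 KO XEN.

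The comparison of KO XEN with WT XEN asks which transcripts differed between the genotypes after the same differentiation. Genes of the primitive endoderm and of its visceral derivative were lower in the knockout cells. Lrp2, the endocytic receptor megalin (ENSMUSG00000027070, chromosome 2, 69424340 to 69586065), stood at 47.7 ± 6.26 CPM in KO XEN and 3884 ± 988 CPM in WT XEN (log2 fold change -6.35 ± 0.27). Sox7, a transcription factor of the primitive endoderm, stood at 2.32 ± 1.12 and 134 ± 32.2 CPM (-5.79 ± 0.50), Cited1, a transcriptional co-regulator, at 2.67 ± 0.489 and 112 ± 2.39 CPM (-5.37 ± 0.45), and Rbp4, the plasma carrier of retinol, at 1.98 ± 0.947 and 76.6 ± 35.9 CPM (-5.21 ± 0.50). Adjusted p for these 4 genes and Ihh, a hedgehog ligand of the visceral endoderm at 1.46 ± 1.03 and 42.2 ± 3.70 CPM, lay between 5.75e-05 and 0.000276 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

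The primitive endoderm regulators held 20 measured genes, 0 higher, 15 lower and 5 not past the threshold (0 and 15 adjusted over the list alone), with a median log2 fold change of -3.16. Primitive endoderm regulators gave camera adjusted p = 1.56e-08 and adjusted p = 0.224 with an estimated correlation. Visceral endoderm markers held 27, 0 higher, 25 lower and 2 not past the threshold (0 and 25 adjusted over the list alone), with a median of -4.76, also with the members at 0 in a group set to their bound. Visceral endoderm markers gave camera adjusted p = 5.66e-10 and adjusted p = 0.169 with an estimated correlation. Parietal endoderm and basement membrane genes went both ways: of 24, 5 were higher, 12 were lower and 7 did not pass (6 and 12 adjusted over the list alone), with a median of -0.86. Parietal endoderm and basement membrane genes gave camera adjusted p = 0.0194 and adjusted p = 0.445 with an estimated correlation. The 3 chains of laminin-111 were lower: Lama1 (ENSMUSG00000032796, chromosome 17, 67697259 to 67822647) at 208 ± 130.1 CPM in KO XEN against 12769 ± 5229.5 in WT XEN (-5.94 ± 0.60), Lamb1 by a log2 fold change of -2.98 ± 0.26 and Lamc1 by -3.12 ± 0.30, with edgeR adjusted p from 0.000213 to 0.000314. P4ha2, a collagen prolyl hydroxylase, was lower too (-2.82 ± 0.23). In the definitive endoderm list of 12 genes, 2 were higher, 6 were lower and 4 did not pass (2 and 6 adjusted over the list alone). Definitive endoderm genes gave camera adjusted p = 0.0979. The list as a whole passed downward without KO ESC C4 (camera adjusted p = 0.0199), KO ESC 5-3_2 (0.0457) or WT XEN B (0.00882), and with line as a block (0.0288), in a range from 0.00882 to 0.654. Its members Sox17, a transcription factor of the endoderm (-4.81 ± 0.66), and Epcam, an epithelial adhesion protein (-3.09 ± 0.26), were lower in KO XEN.

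Pluripotency genes were lower in KO XEN than in WT XEN. Esrrb, a nuclear receptor of naive pluripotency, stood at 0.815 ± 0.0227 CPM in KO XEN, 27.7 ± 5.64 in WT XEN and 655 ± 11 in KO ESC, and Fbxo15, an F-box protein used as an ES cell marker, at 0.618 ± 0.258, 50.8 ± 21.5 and 242 ± 6.52 CPM. Their log2 fold changes between KO XEN and WT XEN were -5.07 ± 0.22 and -6.24 ± 0.40 (adjusted p = 5.75e-05 and 0.000131, edgeR). The naive pluripotency list held 31 genes, 2 higher, 22 lower and 7 not past the threshold (2 and 22 adjusted over the list alone), with a median log2 fold change of -2.81, or -2.71 with the members at 0 in a group set to their bound. Naive pluripotency genes gave camera adjusted p = 5.03e-12 and adjusted p = 0.166 with an estimated correlation. Primed epiblast genes, 17 in number, split into 6 higher, 2 lower and 9 not past the threshold (6 and 2 adjusted over the list alone), and the list did not pass. Primed epiblast genes gave camera adjusted p = 0.382. Among them Dnmt3b, a de novo DNA methyltransferase (-3.98 ± 0.37), was lower and Cdh2, N-cadherin (2.62 ± 0.30), was higher in KO XEN.

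**Figure D2:**
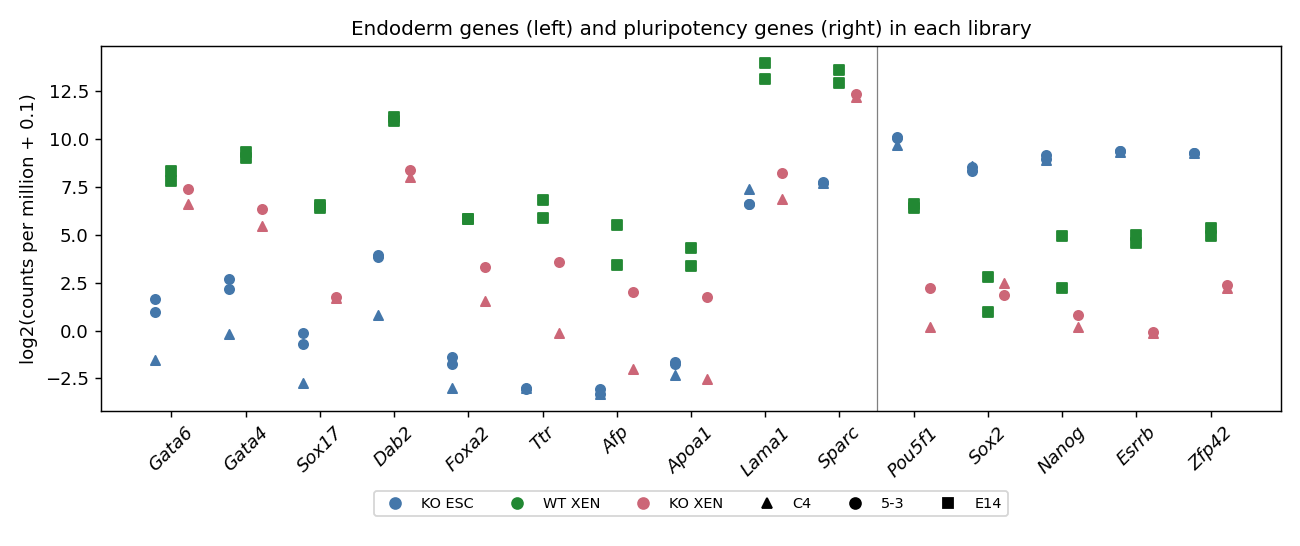
Level of 10 endoderm genes and 5 pluripotency genes in each library, as log2 of CPM plus 0.1, with colour for the group and symbol for the line; those outside the naming rule were chosen after their values were seen. For Lama1 the KO XEN libraries have a mean of 208 CPM and the WT XEN libraries one of 12769 CPM, and for Esrrb the means are 0.815 and 27.7 CPM.

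Genes of fibroblasts, of the interferon response and of the nervous system were higher in KO XEN. Tagln, an actin-binding protein of smooth muscle and fibroblasts, stood at 3814 ± 325 CPM in KO XEN and 310.0 ± 156 in WT XEN (3.62 ± 0.37), and Col5a1, a fibrillar collagen chain, at 834 ± 44 and 56.7 ± 27.3 CPM (3.88 ± 0.34), with edgeR adjusted p of 0.000319 and 0.00021. The fibroblast list held 19 genes, 12 higher, 2 lower and 5 not past the threshold (12 and 2 adjusted over the list alone), with a median log2 fold change of 2.5, also with the members at 0 in a group set to their bound. Fibroblast genes gave camera adjusted p = 0.000128 and adjusted p = 0.329 with an estimated correlation. Interferon response genes included Ifitm3, a membrane protein that restricts virus entry, at 699.6 ± 186 and 22.7 ± 14 CPM (4.95 ± 0.45), and Irf9, a subunit of the interferon-activated transcription factor (2.06 ± 0.21). Of 22 such genes, 21 were higher, 0 were lower and 1 did not pass (21 and 0 adjusted over the list alone), with a median of 3.28. Interferon response genes gave camera adjusted p = 1.49e-12 and adjusted p = 0.265 with an estimated correlation. Neuroectoderm genes, 18 in number, gave 9 higher, 0 lower and 9 not past the threshold (10 and 0 adjusted over the list alone), among them Tubb3, a neuronal tubulin (2.67 ± 0.24), and Dcx, doublecortin (4.54 ± 0.58). Neuroectoderm genes gave camera adjusted p = 0.00109 and adjusted p = 0.224 with an estimated correlation. Primitive streak and mesoderm genes, 21 in number, gave 9 higher, 1 lower and 11 not past the threshold (9 and 1 adjusted over the list alone), with Twist1, a mesodermal transcription factor (2.57 ± 0.37), higher and Eomes, a T-box factor (-2.42 ± 0.40), lower. Primitive streak and mesoderm genes gave camera adjusted p = 0.0106 and adjusted p = 0.445 with an estimated correlation. Pdgfrb, a receptor of mesenchymal cells (3.41 ± 0.30), counts in both the fibroblast and the mesoderm list. Mitochondrial transcripts, given above by library, held a lower share of counts in KO XEN, the group in which these lists were higher.

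Targets of p53 and genes of the retinoic acid and FGF responses were also higher in KO XEN. Cdkn1a, the cell cycle inhibitor p21, stood at 942 ± 137 CPM in KO XEN and 161 ± 53.7 in WT XEN (2.55 ± 0.25, edgeR adjusted p = 0.000279), and the p53 target list of 23 genes had 14 higher, 1 lower and 8 not past the threshold (14 and 1 adjusted over the list alone). The p53 targets gave camera adjusted p = 0.000155 and adjusted p = 0.29 with an estimated correlation. Its members Bbc3, the apoptosis regulator Puma (1.90 ± 0.25), and Plk2, a polo-like kinase (2.25 ± 0.25), were higher. Retinoic acid response genes, 29 in number, had 17 higher, 2 lower and 10 not past the threshold (18 and 2 adjusted over the list alone): the homeobox gene Meis2 (2.27 ± 0.22) was higher, whereas Cyp26a1, which degrades retinoic acid, was lower at 88.2 ± 8.5 against 831 ± 244 CPM (-3.24 ± 0.30). Retinoic acid response genes gave camera adjusted p = 1.85e-05 and adjusted p = 0.169 with an estimated correlation. FGF and ERK response genes, 21 in number, had 13 higher, 2 lower and 6 not past the threshold (13 and 2 adjusted over the list alone), with Dusp5, an ERK phosphatase (3.08 ± 0.38), and Myc, a growth-promoting transcription factor (3.64 ± 0.63), higher. FGF and ERK response genes gave camera adjusted p = 0.00156 and adjusted p = 0.445 with an estimated correlation. For activin and Nodal response genes the counts over 17 were 7 higher, 2 lower and 8 not past the threshold (7 and 2 adjusted over the list alone), and the list did not pass except without WT XEN A (camera adjusted p = 0.0132, range 0.0132 to 0.628). Activin and Nodal response genes gave camera adjusted p = 0.125. Smad7, an inhibitor of the pathway, was higher (1.63 ± 0.22).

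Genes of cell division, of glycolysis and of the amino acid response were lower in KO XEN. Kif11, a kinesin of the mitotic spindle, stood at 10.3 ± 1.62 CPM in KO XEN and 139 ± 43.6 in WT XEN (-3.75 ± 0.29), and Bub1, a spindle checkpoint kinase, at 7.25 ± 1.93 and 97 ± 25.6 CPM (-3.72 ± 0.28), with edgeR adjusted p of 0.000176 and 0.000165. The G2 and mitosis list held 25 genes, 0 higher, 24 lower and 1 not past the threshold (0 and 24 adjusted over the list alone), with a median log2 fold change of -2.58. Mitosis genes gave camera adjusted p = 5.63e-22 and adjusted p = 0.166 with an estimated correlation. DNA replication genes, 25 in number, had 1 higher, 16 lower and 8 not past the threshold (1 and 18 adjusted over the list alone), with Orc1, of the origin recognition complex (-2.32 ± 0.17), and Pola1, the catalytic subunit of polymerase alpha (-3.12 ± 0.28), lower. Replication genes gave camera adjusted p = 0.000231 and adjusted p = 0.351 with an estimated correlation. Endoplasmic reticulum stress and amino acid response genes, 24 in number, had 0 higher, 17 lower and 7 not past the threshold (0 and 17 adjusted over the list alone), with Psat1, of serine synthesis (-2.99 ± 0.21), and Hsp90b1, a chaperone of the endoplasmic reticulum (-2.29 ± 0.19), lower. Stress and amino acid response genes gave camera adjusted p = 9.38e-09 and adjusted p = 0.169 with an estimated correlation. Glycolysis and hypoxia genes, 27 in number, had 2 higher, 16 lower and 9 not past the threshold (2 and 16 adjusted over the list alone), with the phosphofructokinase genes Pfkp (-3.08 ± 0.23) and Pfkl (-2.57 ± 0.23) and the angiogenic factor Vegfa (-2.08 ± 0.17) lower. Glycolysis and hypoxia genes gave camera adjusted p = 1.42e-05 and adjusted p = 0.169 with an estimated correlation.

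Known targets of the miR-290, miR-302 and miR-17 families of ES cells, 20 in number, had 12 higher, 2 lower and 6 not past the threshold (12 and 2 adjusted over the list alone) in KO XEN against WT XEN, with Bcl2l11, the apoptosis regulator Bim (2.07 ± 0.20), higher and Pfkp lower. ES cell microRNA targets gave camera adjusted p = 0.00237 and adjusted p = 0.169 with an estimated correlation. Targets of let-7, 24 in number, had 4 higher, 9 lower and 11 not past the threshold (6 and 9 adjusted over the list alone), and the list did not pass. Let-7 targets gave camera adjusted p = 0.0996. Lin28a, which blocks let-7 maturation, was lower (-4.18 ± 0.43), and its paralog Lin28b was higher (2.89 ± 0.33). In the Argonaute and microRNA machinery list of 20 genes, which did not pass, 3 were higher, 5 were lower and 12 did not pass (3 and 5 adjusted over the list alone), with Tnrc6b, a partner of Argonaute proteins (1.21 ± 0.16), higher and Trim71, a let-7 target (-1.39 ± 0.27), lower. MicroRNA machinery genes gave camera adjusted p = 0.645.

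Largest among the genes that the naming rule takes were rises of Actc1, cardiac actin, to 87.2 ± 1.15 CPM from 0.701 ± 0.210 (6.95 ± 0.59), Stmn4, a stathmin (6.86 ± 0.52), Grik4, a kainate receptor subunit (6.65 ± 0.81), Apol9a, an apolipoprotein L gene with a close paralog (6.61 ± 0.89), and Psmb8, an immunoproteasome subunit (6.33 ± 0.47), with edgeR adjusted p from 0.000155 to 0.00219. Nnat, an imprinted gene, had the largest estimate (7.27 ± 2.34, adjusted p = 0.0352), with 148 CPM in C4 and 6.62 in 5-3, and lost its call without KO XEN C4 (adjusted p = 0.231), WT XEN A (0.101) or WT XEN B (0.169), in a range over the edgeR alternatives from 0.000842 to 0.231. On the lower side stood Apoa2, an apolipoprotein, with 0 counts in KO XEN and at least 164-fold lower than in WT XEN against a floor of 3 counts over the group. Count ratios of WT XEN over KO XEN were 1104-fold (198 to 43641) for Col6a5, a collagen chain, 520.3-fold (93.1 to 20575) for Serpina10, a serpin, and 366-fold (125 to 1775) for Slco4c1, an organic anion transporter, with 95% counting intervals. Bglap3, a gene of the osteocalcin cluster (-8.51 ± 0.43), and Slc23a1, a vitamin C transporter (-8.10 ± 0.61), completed the 6. Serpina10 did not pass without both C4 libraries (edgeR adjusted p = 0.0514, range 1.59e-07 to 0.0514).

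Of 18426 genes tested, 4115 were higher and 4397 lower in KO XEN than in WT XEN, and 3091 and 3397 of these by a log2 fold change of at least 1 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The shared spread includes the 2 undifferentiated 5-3 libraries, which come from the same line. With these summed, 3435 genes were higher and 4361 lower. Without both C4 libraries the counts were 3786 higher and 3871 lower. The count of higher genes fell to 2597 without WT XEN B and to 2697 without KO XEN 5-3. Camera passed 18 of the 27 lists here, and 0 with an estimated correlation. Genotype was not separable from line or culture, since KO XEN comes from 2 edited lines and the labels do not describe separate cultures.

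**Figure D3:**
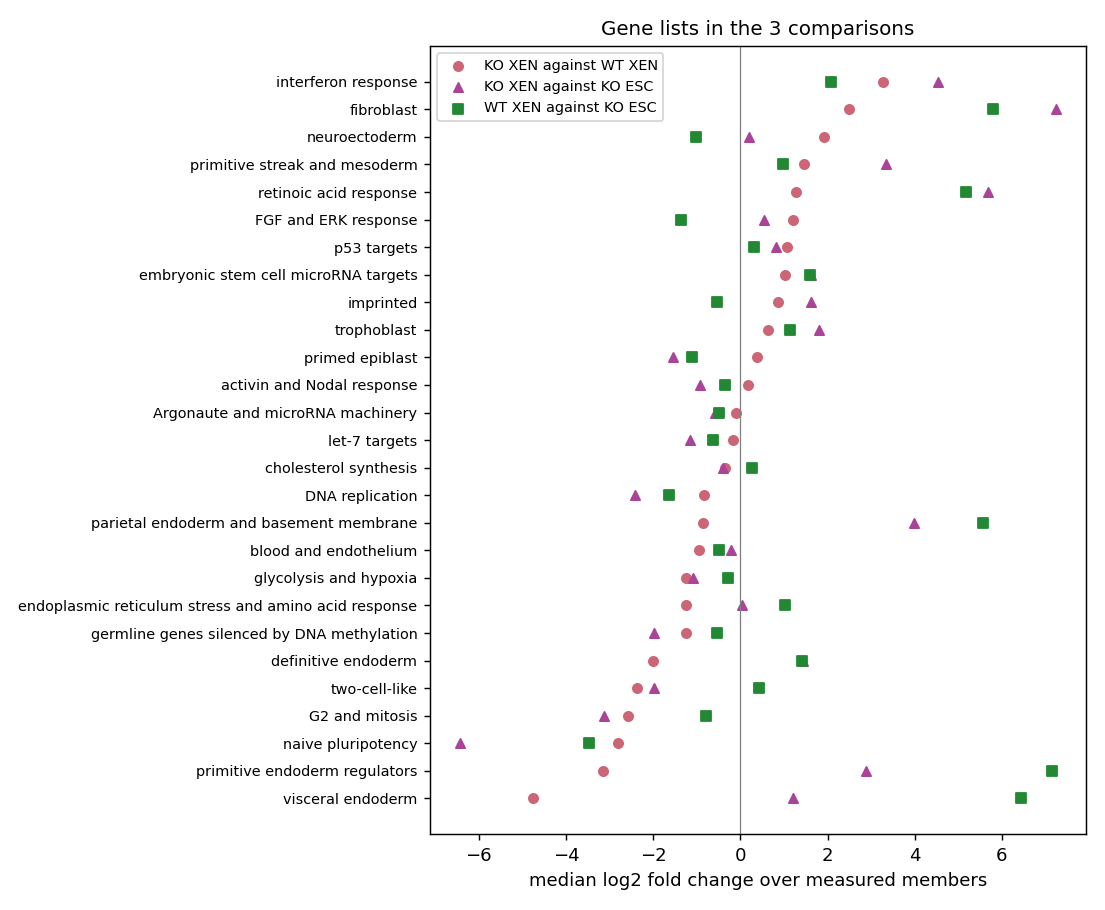
Median log2 fold change of the measured members of each of the 27 gene lists (horizontal axis), with fitted values for members at 0 in a group, in the 3 comparisons, 1 symbol per comparison, sorted by KO XEN against WT XEN. Medians for KO XEN against WT XEN run from -4.76 (visceral endoderm) to 3.28 (interferon response).

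The comparison of KO XEN with KO ESC asks how the knockout cells changed on differentiation. Pluripotency genes fell and genes of basement membrane, retinoic acid response and fibroblasts rose. Esrrb fell from 655 ± 11 to 0.815 ± 0.0227 CPM (-9.64 ± 0.25) and Zfp42, the ES cell marker Rex1, from 617 ± 8.17 to 4.79 ± 0.407 CPM (-7.00 ± 0.22). Hspg2, the basement membrane proteoglycan perlecan, rose from 192 ± 13.4 to 3183 ± 590.4 CPM (4.05 ± 0.18), and Rarb, a retinoic acid receptor, from 0.140 ± 0.0347 to 109 ± 9.29 CPM (9.55 ± 0.27). Adjusted p for these 4 genes lay between 8.84e-07 and 1.63e-06 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

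In this comparison the naive pluripotency list of 31 genes had 0 risen, 31 fallen and 0 not past the threshold (0 and 31 adjusted over the list alone), with a median log2 fold change of -6.43, also with the members at 0 in a group set to their bound. Naive pluripotency genes gave camera adjusted p = 1.31e-24 and adjusted p = 0.0523 with an estimated correlation. Parietal endoderm and basement membrane genes (24) had 23 risen, 0 fallen and 1 not past the threshold (23 and 0 adjusted over the list alone), with a median of 3.98, among them Plat, tissue plasminogen activator (8.75 ± 0.35), and Krt19, an epithelial keratin (5.76 ± 0.23). Parietal endoderm and basement membrane genes gave camera adjusted p = 3.34e-11 and adjusted p = 0.0968 with an estimated correlation. Visceral endoderm markers (27) had 9 risen, 7 fallen and 11 not past the threshold (9 and 7 adjusted over the list alone), with a median of 1.22, or 0.84 with the members at 0 in a group set to their bound. Visceral endoderm markers gave camera adjusted p = 0.67. Stra6, a receptor for the retinol carrier, rose (6.74 ± 0.33), and Spink1, a protease inhibitor, fell (-5.69 ± 0.69). Primitive endoderm regulators (20) had 15 risen, 3 fallen and 2 not past the threshold (15 and 3 adjusted over the list alone), with a median of 2.87: Foxa1, a forkhead factor of endoderm (5.11 ± 0.39), rose, and Lrp2 (-1.93 ± 0.21) and Sall4, a zinc finger factor that ES cells also express (-5.00 ± 0.27), fell. Primitive endoderm regulators gave camera adjusted p = 0.0541. That list passed without any 1 of the libraries other than KO XEN 5-3 (camera adjusted p up to 0.0283) and with line as a block (0.00144), in a range from 0.000104 to 0.684.

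Retinoic acid response genes (29) had 24 risen, 1 fallen and 4 not past the threshold (24 and 1 adjusted over the list alone), with a median log2 fold change of 5.67, also with the members at 0 in a group set to their bound, including Dhrs3, a retinaldehyde reductase (9.14 ± 0.31). Retinoic acid response genes gave camera adjusted p = 2.84e-20 and adjusted p = 0.0523 with an estimated correlation. Fibroblast genes (19) had 17 risen, 1 fallen and 1 not past the threshold (17 and 1 adjusted over the list alone), with a median of 7.23, or 7.63 with the members at 0 in a group set to their bound, and Tagln rose from 5.37 ± 1.04 CPM (9.47 ± 0.40). Fibroblast genes gave camera adjusted p = 1.02e-09 and adjusted p = 0.267 with an estimated correlation. Primitive streak and mesoderm genes (21) had 12 risen, 3 fallen and 6 not past the threshold (12 and 3 adjusted over the list alone), with the forkhead gene Foxf1 (9.12 ± 0.54) risen. Primitive streak and mesoderm genes gave camera adjusted p = 0.0044 and adjusted p = 0.465 with an estimated correlation. Interferon response genes (22) had 20 risen, 2 fallen and 0 not past the threshold (20 and 2 adjusted over the list alone), including Ifih1, a sensor of double-stranded RNA (9.80 ± 0.54). Interferon response genes gave camera adjusted p = 4.63e-09 and adjusted p = 0.435 with an estimated correlation. The p53 targets (23) had 14 risen, 0 fallen and 9 not past the threshold (14 and 0 adjusted over the list alone). The p53 targets gave camera adjusted p = 0.00372 and adjusted p = 0.435 with an estimated correlation. ES cell microRNA targets (20) had 15 risen, 1 fallen and 4 not past the threshold (15 and 1 adjusted over the list alone), with the nuclear receptor gene Nr2f2 (10.71 ± 0.31) risen. ES cell microRNA targets gave camera adjusted p = 2.91e-06 and adjusted p = 0.0523 with an estimated correlation. The share of mitochondrial transcripts was lower in KO XEN than in KO ESC, as given above. Genes of division and glycolysis fell. G2 and mitosis genes (25) had 0 risen, 25 fallen and 0 not past the threshold (0 and 25 adjusted over the list alone). Mitosis genes gave camera adjusted p = 5.04e-17 and adjusted p = 0.106 with an estimated correlation. DNA replication genes (25) had 0 risen, 23 fallen and 2 not past the threshold (0 and 23 adjusted over the list alone). Replication genes gave camera adjusted p = 2.93e-12 and adjusted p = 0.182 with an estimated correlation. Glycolysis and hypoxia genes (27) had 3 risen, 17 fallen and 7 not past the threshold (3 and 17 adjusted over the list alone). Glycolysis and hypoxia genes gave camera adjusted p = 0.00409 and adjusted p = 0.267 with an estimated correlation. Examples were Ect2, which drives cytokinesis (-3.92 ± 0.18), Gins1, of the replicative helicase (-3.21 ± 0.17), and Ldha, lactate dehydrogenase (-2.45 ± 0.17). Germline genes (20) had 0 risen, 10 fallen and 10 not past the threshold (0 and 9 adjusted over the list alone). Germline genes gave camera adjusted p = 0.0168 and adjusted p = 0.435 with an estimated correlation. Targets of let-7 (24) had 4 risen, 15 fallen and 5 not past the threshold (4 and 15 adjusted over the list alone), a call lost with line as a block (camera adjusted p = 0.0546) and without KO ESC C4 (0.0521), in a range from 0.000187 to 0.267. Let-7 targets gave camera adjusted p = 0.0356 and adjusted p = 0.267 with an estimated correlation.

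Col3a1, a fibrillar collagen chain, had 0 counts in KO ESC and was at least 66532-fold higher in KO XEN, and Pcdh7, a protocadherin, at least 5812-fold, each against a floor of 3 counts over the group. The interferon-induced genes Ifi44 and Ifit3b, the second with a close paralog, were at least 3124-fold and 2863-fold higher, and Usp18, an interferon-induced protease (13.69 ± 0.65), and Tnc, the matrix protein tenascin C (14.10 ± 0.33), completed the 6 largest rises under the naming rule. The 6 largest falls all ended at 0 counts in KO XEN: Platr7, a pluripotency-associated transcript, was at least 683-fold lower, H2-M6-ps, a pseudogene of the major histocompatibility complex, 350.0-fold, Prdm14, a regulator of naive pluripotency, 336-fold, Fgf15, a growth factor, 284-fold, Chrna9, a nicotinic receptor subunit, 246-fold and Lrriq4 178-fold. Ago2 stood at 65.8 ± 79 CPM in KO XEN and 37.8 ± 49 in KO ESC (0.79 ± 1.16, edgeR adjusted p = 0.564), and without KO ESC C4 the log2 fold change was 2.78 (adjusted p = 0.0383, range 0.0383 to 0.866). That fit sets both lines in KO XEN against 5-3 alone in KO ESC, and within lines Ago2 went from 94.4 to 122 CPM in C4 and from 9.37 and 9.65 to 9.94 CPM in 5-3. Of 18426 genes, 6405 rose and 6314 fell (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 5995 and 5691 without both C4 libraries. Libraries 5-3_1 and 5-3_2 came from the same line, so that the 3 KO ESC libraries stand for 2 lines. The other 12 lists did not pass (camera adjusted p from 0.0533 to 0.976), and 0 of the 27 passed with an estimated correlation. Imprinted genes were the nearest, and passed upward with line as a block (camera adjusted p = 0.0105) and without KO ESC C4 (0.00732), KO ESC 5-3_1 (0.0471), KO XEN C4 (0.0386) or KO XEN 5-3 (0.00459), in a range from 0.00228 to 0.484.

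WT XEN and KO ESC differ in both genotype and state, and their comparison serves as a reference for the other 2. Endoderm genes were higher in WT XEN: Sparc, a matrix protein of parietal endoderm, stood at 10165 ± 3100.1 CPM against 212 ± 4.63 in KO ESC (5.59 ± 0.22), Lrp2 at 3884 ± 988 against 181 ± 20.7 CPM (4.42 ± 0.21) and Amot, an angiomotin of visceral endoderm, at 639 ± 265 against 6.27 ± 1.29 CPM (6.67 ± 0.32). Cyp26a1 stood at 831 ± 244 against 0.240 ± 0.120 CPM (11.74 ± 0.38), and Zfp42 was lower at 35.3 ± 6.94 CPM (-4.13 ± 0.19). Adjusted p for these 5 genes lay between 2.34e-06 and 4.74e-06 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

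Here the primitive endoderm regulators (20) had 19 higher, 1 lower and 0 not past the threshold (19 and 1 adjusted over the list alone), with a median log2 fold change of 7.15. Primitive endoderm regulators gave camera adjusted p = 5.6e-10 and adjusted p = 0.233 with an estimated correlation. Visceral endoderm markers (27) had 24 higher, 1 lower and 2 not past the threshold (24 and 1 adjusted over the list alone), with a median of 6.44, or 5.68 with the members at 0 in a group set to their bound. Visceral endoderm markers gave camera adjusted p = 9.35e-08 and adjusted p = 0.412 with an estimated correlation. With an estimated correlation 3 lists also passed, those of parietal endoderm and basement membrane, naive pluripotency and retinoic acid response. Parietal endoderm and basement membrane genes (24) had 23 higher, 0 lower and 1 not past the threshold (23 and 0 adjusted over the list alone) and a median of 5.57. Parietal endoderm and basement membrane genes gave camera adjusted p = 3.17e-20 and adjusted p = 0.0487 with an estimated correlation. Naive pluripotency genes (31) had 0 higher, 27 lower and 4 not past the threshold (0 and 27 adjusted over the list alone) and a median of -3.48. Naive pluripotency genes gave camera adjusted p = 1.34e-17 and adjusted p = 0.0366 with an estimated correlation. Retinoic acid response genes (29) had 23 higher, 3 lower and 3 not past the threshold (23 and 3 adjusted over the list alone) and a median of 5.17, also with the members at 0 in a group set to their bound. Retinoic acid response genes gave camera adjusted p = 1.34e-17 and adjusted p = 0.0487 with an estimated correlation. Fibroblast genes (19) had 17 higher, 1 lower and 1 not past the threshold (18 and 1 adjusted over the list alone). Fibroblast genes gave camera adjusted p = 9.35e-08 and adjusted p = 0.412 with an estimated correlation. Interferon response genes (22) had 14 higher, 5 lower and 3 not past the threshold (14 and 5 adjusted over the list alone). Interferon response genes gave camera adjusted p = 0.0129 and adjusted p = 0.728 with an estimated correlation. Endoplasmic reticulum stress and amino acid response genes (24) had 19 higher, 1 lower and 4 not past the threshold (19 and 1 adjusted over the list alone). Stress and amino acid response genes gave camera adjusted p = 0.000953 and adjusted p = 0.412 with an estimated correlation. ES cell microRNA targets (20) had 11 higher, 3 lower and 6 not past the threshold (11 and 3 adjusted over the list alone), with Tgfbr2, a TGF-beta receptor (6.36 ± 0.41), higher. ES cell microRNA targets gave camera adjusted p = 0.00101 and adjusted p = 0.117 with an estimated correlation. Mitosis genes (25) had 0 higher, 17 lower and 8 not past the threshold (0 and 17 adjusted over the list alone). Mitosis genes gave camera adjusted p = 0.00171 and adjusted p = 0.493 with an estimated correlation. DNA replication genes (25) had 0 higher, 21 lower and 4 not past the threshold (0 and 21 adjusted over the list alone), with Pcna, the replication clamp (-1.89 ± 0.16), lower in WT XEN. Replication genes gave camera adjusted p = 5.35e-09 and adjusted p = 0.345 with an estimated correlation. Mitochondrial transcripts held a lower share in WT XEN than in KO ESC, as given above.

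Against a floor of 3 counts over the KO ESC group, Col3a1 was at least 11536-fold higher in WT XEN, the glucuronosyltransferase genes Ugt2b34 and Ugt1a7c, the second of a cluster with shared exons, at least 2747-fold and 934-fold, and Pcdh7 at least 685-fold, with Tnc (11.75 ± 0.31) and Cyp26a1, given above, next. Chrna9 was at least 386-fold lower. Count ratios of KO ESC over WT XEN, with 95% counting intervals, were 1229-fold (220.3 to 48545) for Napsa, an aspartic protease, 785-fold (141 to 31035) for Stmn3, a stathmin, 669-fold (185 to 5528) for Fgf15, 606-fold (207 to 2938) for Tgm3, a transglutaminase, and 552-fold (153 to 4564) for Pou4f2, a neural transcription factor. Ago2 was higher in WT XEN (3.45 ± 1.20, edgeR adjusted p = 0.0352), but not past the threshold without KO ESC 5-3_1 (adjusted p = 0.0766), KO ESC 5-3_2 (0.0862), WT XEN A (0.0761) or WT XEN B (0.0903), in a range from 6.15e-06 to 0.0903. Of 18426 genes, 5937 were higher and 5584 lower in WT XEN (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 6081 and 5654 without both C4 libraries. The remaining 16 lists did not pass (camera adjusted p from 0.0583 to 0.799). Of these, FGF and ERK response genes passed downward without KO ESC C4 (camera adjusted p = 0.0325), KO ESC 5-3_1 (0.05 after rounding), KO ESC 5-3_2 (0.048) or WT XEN A (0.000608), in a range from 0.000608 to 0.728. Primed epiblast genes passed downward without WT XEN A (camera adjusted p = 0.0117, range 0.0117 to 0.728).

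Some lists gave a median and a mean or test of opposite sign, and none of these passed camera. In KO XEN against KO ESC they were FGF and ERK response (median 0.54, mean -0.02), endoplasmic reticulum stress and amino acid response (median 0.03, mean -0.34), whose median also turned sign when library size alone scaled the counts, activin and Nodal response (median -0.92, camera upward) and blood and endothelium (median -0.22, or -1.12 with the members at 0 in a group set to their bound, camera upward). In WT XEN against KO ESC they were imprinted genes (median -0.54, mean 0.42), blood and endothelium (median -0.48, also with the members at 0 in a group set to their bound, mean 0.67) and glycolysis and hypoxia (median -0.28, mean 0.18).

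The changes from KO ESC to KO XEN and from KO ESC to WT XEN went together across genes, as for Col3a1, Tnc and Pcdh7, which rose in both, and Esrrb, Zfp42 and Chrna9, which fell in both. Across the 18426 genes, which are not independent replicates, Pearson r was 0.774 and Spearman rho 0.747, and the 4 pairs of a KO XEN with a WT XEN library gave r from 0.692 to 0.802. Both changes share the KO ESC libraries, which alone makes them correlate: in 20 simulations of unchanged groups the mean r was 0.345 and the mean covariance 0.117, against a covariance of 5.64 in the data. Changes had the same sign in 78.9% of genes, against a mean of 62.8% in these simulations. By the edgeR calls 4454 genes rose in both and 4235 fell in both, against 2064 and 1913 expected for independent calls, a reference that does not allow for the shared libraries, and 546 were called in opposite directions. Lrp2 was among these, higher in WT XEN and lower in KO XEN than in KO ESC. The difference of WT XEN from KO ESC holds genotype as well as state, so it is not the change of wild-type cells on differentiation.

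Whether lines C4 and 5-3 changed differently on differentiation was tested as an interaction. With edgeR quasi-likelihood and Benjamini-Hochberg adjustment 0 of 18426 genes passed, 1844 had an unadjusted p under 0.05, and the DESeq2 Wald test passed 225. Of the 4 combinations of line and state 3 hold 1 library, and the spread, with 2 residual degrees of freedom, came from the 5-3 KO ESC and the WT XEN pairs, so that the DESeq2 calls do not show that the lines differed. In simulated data with these group sizes the edgeR test called 9% of genes with a 4-fold and 60% with a 16-fold difference.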

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

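Tests of wild-type cells in the C4 library, of foreign cells in the 5-3 library, of depth and of undifferentiated cells were chosen after the result each addresses was seen. For the change on differentiation in line C4 against 5-3 the DESeq2 Wald test called 225 genes, whereas edgeR called 0. Of the 4 combinations of line and state 3 hold 1 library, so that the spread comes from the 5-3 KO ESC and the WT XEN pairs, and these calls do not show that the lines differed. Pga5, a pepsinogen gene, and Plac8 had the smallest p and were chosen after their values were seen, with a log2 change in C4 minus that in 5-3 of -7.06 and -5.23. Pga5 stood at 1.31 CPM in C4 and 71.7 in 5-3 KO XEN, and at 3.86 in C4 and 1.63 and 1.58 in 5-3 KO ESC, and Plac8 at 3.41 and 29.4 CPM in KO XEN and at 19, 5.02 and 3.80 in KO ESC, in the same order of lines. No explanation of these values was tested.

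Ago2 transcript remained in the libraries labelled C4, at 122 CPM in KO XEN. Wild-type XEN cells mixed into that library would need a share of 27.7%. Among 65 genes with at least 50 CPM in WT XEN and under 5% of it in 5-3 KO XEN, the median level in C4 KO XEN was 1.17% of WT XEN (bootstrap 95% interval 0.922 to 1.82), and all 65 lay under that share, which argues against such a mixture. An edited allele that is still transcribed may leave this transcript, which gene counts do not resolve. The position of the edit is not given in the sources used here.

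If genes higher in KO XEN than in WT XEN came from cells of another type with intact Ago2 mixed into 5-3 KO XEN, those cells would have to carry the excess of these genes, 30.0% of counts, with at most 37.0 CPM of Ago2 themselves, against 394 CPM in the lower WT XEN library and a limit of 131 CPM set for the test. Ago2 was not measured here in other cell types. Cells at or above that limit are excluded as a source of the whole set. Those from 37.0 to 131 CPM lie above the bound but within the margin set for the test, and cells with less Ago2 stay open. For the fibroblast list alone, an excess of 1.42% of counts, they could have up to 783 CPM, so fibroblasts cannot be told apart from knockout cells that express these genes. Lower depth of C4 KO XEN does not explain them either, as 86.8% of the genes remained higher after thinning all libraries to its total. Foreign cells in C4 KO XEN, where Ago2 transcript remained, a change of state in the knockout cells, a difference between the lines and the wild-type cells and a difference in culture stay open and untested.

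Pluripotency genes were higher in WT XEN than in KO XEN, which undifferentiated cells left in the WT XEN libraries might explain. Such cells would bring every ES-restricted gene at about an equal share of its KO ESC level. Of 47 such genes, with at least 100 CPM in KO ESC and under 2% of it in KO XEN, the median was 5.30% of KO ESC in A and 3.08% in B. Their 5th percentile was 0.577% and 0.276%. The 22 pluripotency genes called lower in KO XEN than in WT XEN had a median of 15.2% and 10.4%, with members up to 102% and 114%. The larger ratio of the percentile to this median was 0.0379. It sets the low end of 1 set against the middle of genes chosen for a high level in WT XEN. Sox2 stood at 1.88% and 0.504% of KO ESC and Pou5f1 at 9.53% and 8.41%. Esrrb, at 4.83% and 3.61%, and Zfp42, at 6.52% and 4.93%, lay nearer the median of the 47 genes. Nanog stood at 5.84% and 0.877%. These markers were picked after their values were seen. Within the 47 genes, the distance of percentile and median argues against such cells as their only source. This holds only if wild-type ES cells have the levels of KO ESC. For the 22 pluripotency genes the ratio cannot decide, given how they were chosen. A part from such cells and a slower loss of some of these transcripts in WT XEN stay open.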

How the results depend on the processing

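The fit without both C4 libraries and the thinned libraries were chosen after the data were seen. Counts of called genes in the 3 comparisons stayed within 1.5 times under every alternative run, apart from genes higher in KO XEN than in WT XEN, which ranged from 2597 (without WT XEN B) to 4641 (without KO ESC C4) on leaving out a library and gave 2697 without KO XEN 5-3. Such counts do not show that the same genes were called. In a fit of only KO XEN and WT XEN, 82.8% of the genes called higher and 88.0% of those called lower stayed called. Both shares were smaller without WT XEN B, KO XEN C4 or KO XEN 5-3. For the difference between lines DESeq2 called 225 genes and edgeR 0. Camera with an estimated correlation, which also rests on the 4 residual degrees of freedom, called 0, 0 and 3 lists. The order is KO XEN against WT XEN, KO XEN against KO ESC and WT XEN against KO ESC. In the same order fry called 21, 17 and 21. For KO XEN against WT XEN fry also called 3 lists downward that camera at the preset correlation did not. They were let-7 targets (fry adjusted p = 0.0051), blood and endothelium (0.0185) and definitive endoderm (0.0328). Definitive endoderm genes also passed camera after thinning (adjusted p = 0.0161). The correlation of the changes in KO and WT XEN ranged from 0.715 (without KO XEN 5-3) to 0.788 (without WT XEN B) on leaving out a library, and was 0.798 in genes with a mean of at least 10 CPM in the highest group. The causes were not tested. Over named genes and alternatives, 5558 results kept their side of the threshold, 31 lost and 27 gained it, and over lists 880 kept, 42 lost and 50 gained it, with 0 calls reversed. Scaling by library size alone moved the median of all genes to -0.15 in KO XEN against KO ESC and -0.12 in WT XEN against KO ESC (log2), from -0.08 and -0.03, and DESeq2 size factors to -0.10 in the first. Where a group was left with 1 library, it was assumed to vary like the others. At this depth a gene with 0 counts in a KO XEN group is compatible with up to 0.0648 CPM.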

Other observations

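In this part the fit without both C4 libraries and the microRNA tests were chosen after the data were seen, the microRNA tests before their own result. Imprinted genes were higher in KO XEN than in WT XEN: of 30, 11 were higher, 1 was lower and 18 did not pass (11 and 1 adjusted over the list alone), with a median log2 fold change of 0.87. Imprinted genes gave camera adjusted p = 0.00461 and adjusted p = 0.304 with an estimated correlation. Slc38a4, an amino acid transporter, stood at 1759 ± 386 CPM in KO XEN and 148 ± 58.6 in WT XEN (3.57 ± 0.38), Cdkn1c, a cell cycle inhibitor, at 144 ± 44.6 and 13.2 ± 1.96 CPM (3.45 ± 0.47), and Ndn, necdin, at 136 ± 14.8 and 20.1 ± 3.28 CPM (2.76 ± 0.23), with edgeR adjusted p from 0.000202 to 0.000912. Germline genes silenced by DNA methylation were lower: of 20, 0 were higher, 9 were lower and 11 did not pass (0 and 9 adjusted over the list alone), with a median of -1.25, and the list did not pass without WT XEN A (camera adjusted p = 0.0899, range 0.00224 to 0.373). Germline genes gave camera adjusted p = 0.0171 and adjusted p = 0.373 with an estimated correlation. Dazl, an RNA-binding protein of germ cells (-3.95 ± 0.65), and Sycp3, of the synaptonemal complex (-3.04 ± 0.31), were among them.

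Of other cell types in KO XEN against WT XEN, trophoblast genes (18) had 6 higher, 3 lower and 9 not past the threshold (6 and 3 adjusted over the list alone), with Gata3 (2.40 ± 0.33) and Gata2 (3.41 ± 0.41), transcription factors that other lineages also use, higher and Tead4, of early trophoblast (-2.06 ± 0.18), lower. Trophoblast genes gave camera adjusted p = 0.231. The trophoblast list passed upward without KO XEN 5-3 (camera adjusted p = 0.0369, range 0.0369 to 0.54). Blood and endothelium genes (10) had 1 higher, 4 lower and 5 not past the threshold (1 and 5 adjusted over the list alone), with Kdr, a VEGF receptor (1.24 ± 0.23), higher and Cdh5, VE-cadherin (-3.71 ± 0.76), lower. Blood and endothelium genes gave camera adjusted p = 0.332. Genes of the 2-cell-like state (15) had 1 higher, 0 lower and 14 not past the threshold (1 and 0 adjusted over the list alone), with Sp110, which interferon also induces (4.46 ± 0.76), higher and a median log2 fold change of -2.38, or -2.23 with the members at 0 in a group set to their bound. The 2-cell-like genes gave camera adjusted p = 0.18. The list passed downward without both C4 libraries, with 1 member higher and 7 lower (camera adjusted p = 0.00492), and with line as a block (0.026), in a range from 0.00492 to 0.722. Zscan4d stood at 0.269 ± 0.338 and 3.15 ± 1.32 CPM (-3.89 ± 1.49, edgeR adjusted p = 0.0643), and the Zscan4 genes are close paralogs. It passed without KO ESC C4 (adjusted p = 0.0138), without both C4 libraries (0.00679) and with line as a block (0.00121), in a range from 0.00121 to 0.271. Cholesterol synthesis genes (24) had 0 higher, 6 lower and 18 not past the threshold (0 and 6 adjusted over the list alone), with Insig1, a sterol sensor (-3.37 ± 0.47), and Stard4, a sterol carrier (-1.79 ± 0.25), lower, and the list passed downward without WT XEN B (camera adjusted p = 5.16e-05) or KO XEN 5-3 (0.0275), in a range from 5.16e-05 to 0.88. Cholesterol synthesis genes gave camera adjusted p = 0.0996.

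Loss of Ago2 might lower repression of predicted microRNA targets, which would be higher in KO XEN than in WT XEN. For each of 6 families log2 fold changes were adjusted for length and GC content of the 3' untranslated region and for expression. The difference in their mean between genes with and without a seed match was ranked among control 7-mers of the same base composition, over 10215 genes. The percentile was 28.7 for the family of miR-290 and miR-302, 48.2 for the miR-17 family, 8.67 for miR-26, 37.4 for miR-15/16 and 28.5 for miR-30, within the controls, so that these families cannot be told apart from no effect. For let-7 it was 0, below all 104 controls, with a shift of -0.08 against a control range from -0.02 to 0.16 (two-sided permutation test against control 7-mers, p = 0.019, adjusted p = 0.114 over 6 families). This unadjusted p is the smallest that 104 controls can give, and the direction is opposite to lower repression by let-7. The shift did not pass the correction, but beside the p of the other families 104 controls could give no smaller adjusted p. The corrected test thus could not have been passed. A like limit held for miR-15/16 with 99 controls and miR-30 with 179, which could not have passed alone.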
